A study of Homo sapiens with 10 samples.

How the data were processed

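Polyadenylated RNA was sequenced from BJ cells, an established line of human dermal fibroblasts, 72 hours after ectopic expression of a control empty vector, of p63, or of p63 together with KLF4. There were 10 libraries in 5 groups of 2: control, p63, p63 with KLF4, a p63 mutant named for the DBD with KLF4, and a p63 mutant named for the SAM domain with KLF4. DBD and SAM are the usual abbreviations for the DNA-binding domain and the sterile alpha motif of p63; the residues changed are not given in the sources used here. The series design calls the libraries biological duplicates and names the sequencer as a NextSeq500. The labels name no group with KLF4 alone.

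The deposited table holds whole-number counts of reads per gene symbol, 1 column per library, with no normalization, as the values and their unequal totals show. The submitters' processing notes name STAR, featureCounts, bedtools and DESeq2, and the builds GRCh37 and hg19, with no versions and no roles. The per-gene counts deposited by the authors are headed as RefSeq gene symbols. How reads that map to several places were handled, and whether strand was used, is not given in the sources used here. Counts of near-identical paralogs (KRT6A and KRT6B, the CST cystatins, HBA1 and HBA2, the SPRR and LCE genes) and of overlapping or antisense genes are uncertain for that reason. No coordinates are given, as the reference held was of another build.

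Library totals ran from 13805531 to 39993477 counts, and 18326 to 20749 of the 27135 gene symbols had at least 1 count in a library. The 10 most abundant genes took 5.1% to 7.7% of each library. A count of 3 in a library, the limit that a count of 0 allows, corresponded to 0.0743 CPM in the deepest library and 0.201 CPM in the shallowest. Such limits and the 95% counting intervals cover counting error only. CPM were computed from the deposited counts with edgeR's cpm and TMM factors.

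The groups were taken from the sample labels. Each test, the groups in it, 25 gene lists, the rule for named genes and the alternative settings listed further on, except 4, were fixed before the data were examined. Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest), with TMM factors and edgeR's filterByExpr by group. This left 16462 genes. All 10 libraries entered one model with a term per group, so that the groups shared the estimate of the spread, and 8 pairwise contrasts were tested. A further contrast compared p63 with KLF4 minus p63 against the DBD mutant with KLF4 minus control. P-values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. Adjusted p-values of single genes are from this test unless another tool is named. A fold against a group with 0 counts is given as a lower bound, computed against 3 counts over the group. With 1 to 3 counts in a group the ratio of count rates is given with its 95% counting interval.

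The gene lists cover basal keratinocyte genes, keratinocyte differentiation and cornification, epithelial junction and polarity, epithelial and epidermal transcription regulators, orofacial cleft and craniofacial development, fibroblast matrix and identity, contractile and TGF-beta response genes, cell cycle, p53 targets, interferon response, inflammatory cytokines and NF-kB, Notch, Wnt, HOX genes, cholesterol synthesis, unfolded protein and amino acid stress, heat shock proteins, glycolysis and hypoxia, cytosolic ribosomal proteins, mitochondrially encoded genes, and markers of melanocytes, endothelium, leukocytes, neurons and muscle. Of these, 24 could be tested. Each list was tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The tests were repeated with an estimated correlation and with fry, which asks whether the members of a list move one way on balance and compares them with no other genes. Members called by edgeR were counted over all genes tested and again adjusted over the list alone.

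TP63 and KLF4 were given for every library first. In the 5 main comparisons, the named genes were the 5 with the largest positive and the 5 with the largest negative log2 fold change among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups, with TP63, KLF4, XIST and Y-linked genes left out. To these were added, from each list, up to 4 called members with a mean of at least 1 CPM, by size of change, or up to 2 of the most abundant members where none was called. The 5 main comparisons were p63 against control, p63 with KLF4 against control and against p63, and each mutant with KLF4 against p63 with KLF4. In the other comparisons up to 3 genes in each direction were named by the first rule. The text prints a selection of these, mostly those whose call remained when any 1 library was left out. The values of 1 list member are not reported here.

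Comparisons that share libraries were set beside 20 simulations of unchanged groups. Overlaps were set beside independent lists, the product of the counts of calls divided by the genes tested. The alternatives were size factors by DESeq2's median of ratios, library totals as the only scaling, no filter or a minimum mean of 1 CPM, DESeq2 1.42.0, limma-voom, fits of only the groups compared, a replicate block, TP63 and KLF4 left out, an adjusted p under 0.01, a minimum change of 2-fold, and each library left out in turn. Another 4, on the p63 pair and the second replicates of both mutants, were added after seeing the data.

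The edgeR step was tested on data simulated at the real libraries' means with equal spread in all groups. There 200 genes changed, 50 at each of 4 sizes. At log2 changes of 1, 2, 3 and 4, it recovered 14%, 56%, 84% and 92% for p63 against control among 16033 genes. For p63 with KLF4 against control the shares were 16%, 60%, 86% and 94% among 16034 genes, and against p63 they were 22%, 54%, 84% and 84% among 16028 genes. For the DBD mutant they were 18%, 62%, 82% and 86% against control among 16042 genes. They were 14%, 62%, 86% and 88% against p63 with KLF4 among 16017 genes. For the SAM mutant against p63 with KLF4 they were 16%, 62%, 86% and 90% among 16028 genes. Unchanged genes called ran from 3 for p63 against control to 10 for the SAM mutant against p63 with KLF4. Unequal spread was not covered.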

Results

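RNA was measured in BJ fibroblasts that expressed an empty vector (control), p63, p63 with KLF4, or the DBD or SAM mutant of p63 with KLF4. Each group had 2 libraries. The libraries held 21275977 and 27402664 counts in control, 13805531 and 24528037 in p63, and 39993477 and 33382462 in p63 with KLF4. They held 23201570 and 24848279 counts with the DBD mutant and 20197337 and 21464653 with the SAM mutant. Levels are group means in CPM ± SD, and changes log2 fold changes with edgeR's adjusted p. The standard error (SE) was back-calculated from the test.

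TP63 and KLF4, expressed ectopically, were examined first in every library. TP63, a transcription factor of stratified epithelia, stood at 0.294 and 0 CPM in the control libraries, 840 and 821 CPM in p63, and 720 and 684 CPM in p63 with KLF4. It stood at 453 and 502 CPM with the DBD mutant and at 288 and 400 CPM with the SAM mutant. KLF4, a zinc finger transcription factor of the suprabasal epidermis, stood at 23.4 and 17.6 CPM in control, 32.8 and 31.7 in p63, 1050 and 1030 in p63 with KLF4, 865 and 661 with the DBD mutant, and 703 and 522 with the SAM mutant. Against p63 with KLF4, the log2 fold change of TP63 was -0.56 (SE 0.35, adjusted p = 0.323) with the DBD mutant and -1.03 (SE 0.35, adjusted p = 0.184) with the SAM mutant, neither past the threshold. That of KLF4 was -0.45 (adjusted p = 0.207) and -0.76 (adjusted p = 0.122). Between p63 and control KLF4 differed by 0.66 (SE 0.22, adjusted p = 0.0744).

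**Figure D1:**
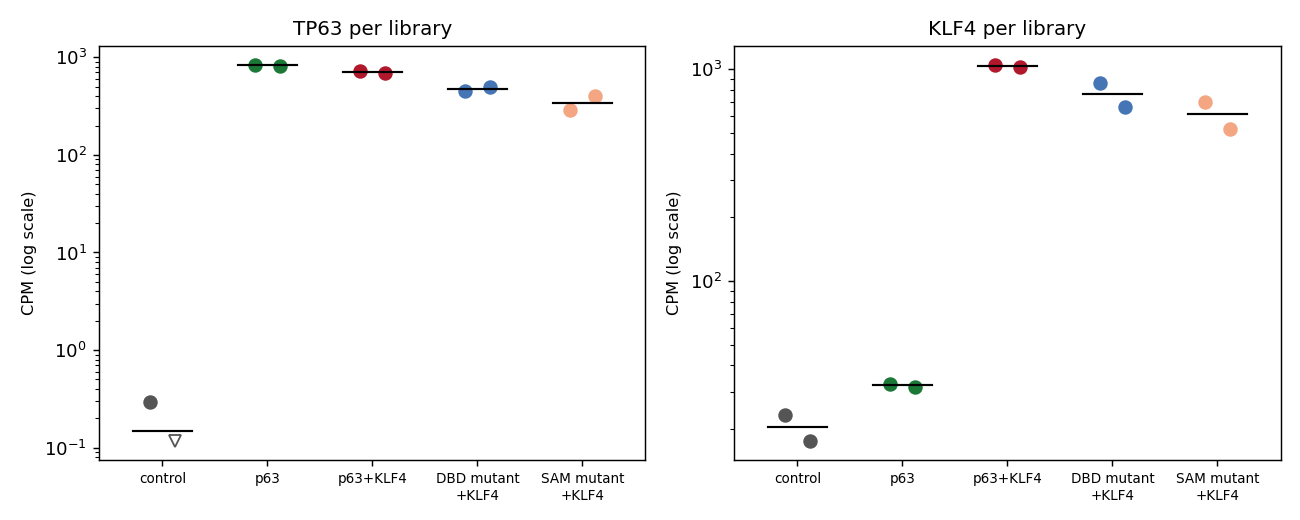
TP63 and KLF4 in each of the 10 libraries, in CPM on a log axis, with points for libraries, black lines for group means, and open triangles at the level of 3 counts for libraries below it. TP63 was at 288 CPM or more in each library outside control, and KLF4 at 522 CPM or more in each library of the 3 groups with KLF4.

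The spread between replicates was uneven. The biological coefficient of variation was 0.0362 for the p63 pair, 0.22 for p63 with KLF4, 0.292 for control, 0.323 for the SAM mutant and 0.324 for the DBD mutant. The p63 libraries still differed by more than the sampling noise, with a chi-square of 3.03 per degree of freedom against 73.5 to 118 in the other pairs, and were counted as 2 samples, as the series design names them. This sets them apart only from 1 library given in duplicate and does not show separate cultures. Principal component 1 held 44.2% of the variance of log2 CPM, and component 2, which set the p63 pair apart at scores of 98.4 and 96.5, held 28.4%. On component 3, with 9.8%, replicate 2 of the DBD mutant (61.2) and replicate 2 of the SAM mutant (56.1) stood apart from their own replicates 1.

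**Figure D2:**
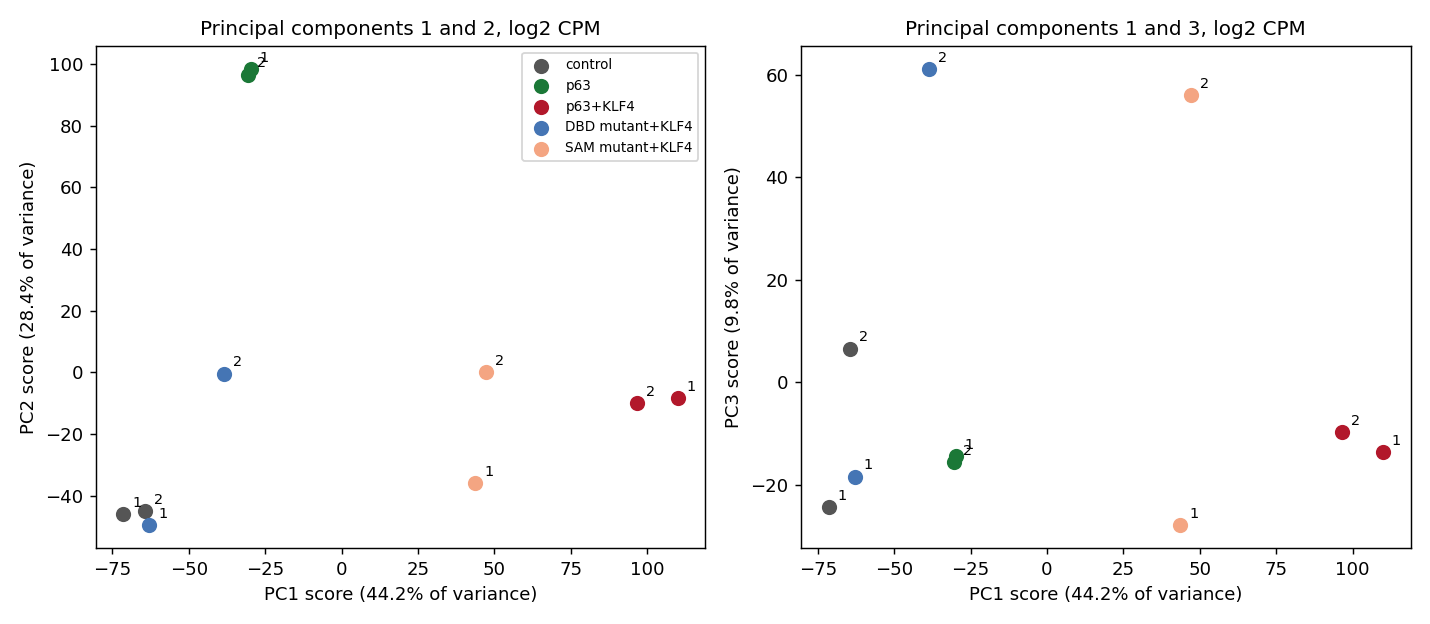
Principal component scores of log2 CPM, components 1 and 2 at left and 1 and 3 at right, with a point for each of the 10 libraries, coloured by group and marked with the replicate number. The p63 pair lies at 98.4 and 96.5 on component 2, and the second replicates of the DBD and SAM mutants lie at 61.2 and 56.1 on component 3.

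The first comparison asked which genes moved with p63 in the absence of KLF4. ITGB4, an integrin chain of hemidesmosomes, rose 54.9-fold from 6.68 ± 3.48 CPM in control to 369 ± 47.5 CPM with p63 (log2 5.78, SE 0.50, adjusted p = 0.000902). S100A2, a calcium-binding protein of basal epithelium, rose 40.6-fold to 241 ± 2.39 CPM (SE 0.38, adjusted p = 0.000402). KRT14, the type I keratin of the basal layer, rose 32.6-fold but reached 8.03 ± 1.18 CPM (SE 0.77, adjusted p = 0.00479). FLG, which encodes filaggrin, rose 9.76-fold to 84.6 ± 0.792 CPM (adjusted p = 0.00224). Of the 28 basal keratinocyte genes tested, 14 rose and 2 fell, and 19 rose and 3 fell adjusted over the list alone. Their median log2 fold change was 1.84 (camera adjusted p = 1.66e-06, and adjusted p = 0.137 with an estimated correlation). The number that rose was 7 without p63 replicate 1 and 8 without p63 replicate 2, and the number that fell was 0 without control replicate 1 or either p63 library and 1 without control replicate 2. Among 28 differentiation and cornification genes 6 rose, also 6 adjusted over the list alone. Their median was 1.39, or 0 with the 14 members at 0 counts in a group at their bound (camera adjusted p = 0.0236, and adjusted p = 0.348 with an estimated correlation). This call ended without control replicate 2 (adjusted p = 0.0739) and p63 replicate 2 (adjusted p = 0.0521), and the members that rose numbered 3 without control replicate 2 and 2 without either p63 library. The median was 0.52 without control replicate 2, 0 without p63 replicate 2, and also over 1.5 times lower without p63 replicate 1 or replicate 1 of p63 with KLF4.

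Junction and transcription regulator genes moved in part. The tight junction protein F11R rose 18.9-fold to 146 ± 1.25 CPM (log2 4.24, SE 0.46, adjusted p = 0.00157). In the list of 42 junction and polarity genes 14 rose and 3 fell, and 15 and 5 adjusted over the list alone, with a median of 1.28, or 1.09 with members at 0 counts at their bound (camera adjusted p = 0.00342, and adjusted p = 0.137 with an estimated correlation). The number that rose was 9 and 8 without p63 replicates 1 and 2, where the latter median was 0.76, and the number that fell was 5 without control replicate 1. Over the 31 epithelial and epidermal transcription regulators 10 rose and 1 fell, and 11 and 2 adjusted over the list alone, with a median of 0.80 (camera adjusted p = 0.00869, and adjusted p = 0.484 with an estimated correlation). That call ended without control replicate 2 (adjusted p = 0.0519), where 4 rose, and 3 rose without either p63 library. The member that fell was no longer called without p63 replicate 1, and 2 fell without control replicate 1 or either SAM mutant library. The 51 orofacial cleft and craniofacial genes went both ways, with 14 higher and 9 lower, 15 and 11 adjusted over the list alone, and a median of 0.42 (camera adjusted p = 0.345). Those counts were 8 higher without control replicate 2, 6 and 2 without p63 replicate 1, and 4 and 1 without p63 replicate 2.

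Many inflammatory genes rose with p63. The cytokine gene CSF3 was at 7.51 ± 0.872 CPM against 0 counts, at least 112-fold higher (adjusted p = 0.00171), and CSF2 rose 85.1-fold (SE 0.63, adjusted p = 0.00106). Of 37 inflammatory cytokine and NF-kB genes 23 rose and 1 fell, and 29 and 2 adjusted over the list alone, with a median of 2.24 (camera adjusted p = 3.39e-10, and adjusted p = 0.348 with an estimated correlation). The number that rose was 12 without control replicate 2, 12 without p63 replicate 1 and 11 without p63 replicate 2, and 2 fell without control replicate 2. In the interferon response list 14 of 41 genes rose and 0 fell, and 19 and 0 adjusted over the list alone, with a median of 1.44 (camera adjusted p = 1.66e-06, and adjusted p = 0.587 with an estimated correlation). The number of interferon genes that rose depended on single libraries, with 25 without control replicate 1 (median 2.24), 2 without control replicate 2, 0 and 1 without p63 replicates 1 and 2, and 9 without either library of p63 with KLF4. The p63 pair had the smallest replicate spread (0.0362).

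Some fibroblast genes fell with p63. PDGFRB, a growth factor receptor of mesenchymal cells, fell 5.58-fold from 183 ± 3.57 to 32.7 ± 2.09 CPM (log2 -2.48, SE 0.22, adjusted p = 0.00094). EDIL3, a secreted matrix protein, fell 195-fold from 90.2 ± 44 to 0.437 ± 0.144 CPM (log2 -7.61, SE 0.47, adjusted p = 0.00021). Of 53 matrix and fibroblast identity genes 24 fell and 2 rose, and 30 and 3 adjusted over the list alone, with a median of -0.76 (camera adjusted p = 6.54e-07, and adjusted p = 0.348 with an estimated correlation). The number that fell was 10 without control replicate 2 and 4 without either p63 library, and 1 rose without control replicate 1 and 0 without either p63 library. Of 30 contractile and TGF-beta response genes 13 fell and 0 rose, and 14 and 0 adjusted over the list alone, with a median of -1.01 (camera adjusted p = 0.000208, and adjusted p = 0.587 with an estimated correlation). Their number was 7 without control replicate 2 and 3 without either p63 library. HOXD10, a homeobox gene of limb patterning, fell from 15.3 CPM in control to 3 counts over both p63 libraries, a ratio of count rates of 206 (95% interval 70.3 to 1000), and HOXD11 fell 78.1-fold (log2 -6.29, SE 0.36, adjusted p = 0.00016). Of 25 HOX genes 4 fell and 2 rose, also 4 and 2 adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.119). Those 2 were not called without either library of control, p63 or p63 with KLF4, and 1 was called without any 1 library of the mutants.

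Other gene lists were examined between p63 and control. Of 72 cytosolic ribosomal protein genes 4 fell, and 0 adjusted over the list alone, with a median of -0.69 (camera adjusted p = 4.31e-08, and adjusted p = 0.587 with an estimated correlation). These 4 were 0 without control replicate 1 (median -0.41) or either p63 library and 2 without either SAM mutant library. Of 41 p53 target genes 8 rose and 5 fell, and 9 and 8 adjusted over the list alone, with a median of -0.21 (camera adjusted p = 0.817). The p53 targets that rose numbered 3 without control replicate 2 or p63 replicate 1 and 2 without p63 replicate 2, and those that fell 2 and 8 without control replicates 1 and 2 and 1 without either p63 library. Of 45 cell cycle genes 1 fell, and 0 adjusted over the list alone, with a median of -0.54 (camera adjusted p = 0.0622). That number was 10 without control replicate 1, 0 without either p63 library and 2 without either DBD mutant library. In the glycolysis and hypoxia list of 31 genes 3 rose and 1 fell, also 3 and 1 adjusted over the list alone, with a median of -0.17, a mean of 0.10 and a camera direction that was down (adjusted p = 0.817). The rising glycolysis genes numbered 1 without either p63 library, and 2 fell without either control library. Of 30 unfolded protein and amino acid stress genes 1 fell, the chaperone cofactor gene SDF2L1 (3.01-fold, adjusted p = 0.00372), also 1 adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.193), and 2 fell without control replicate 1 or either library of p63 with KLF4. Of 14 neural markers 4 fell and 1 rose, also 4 and 1 adjusted over the list alone, with a median of 0.40, a mean of 0.16 and a camera direction that was down (adjusted p = 0.514). The neural markers that fell numbered 2 without control replicate 1 or p63 replicate 1 and 1 without p63 replicate 2, and those that rose 2 without control replicate 1 and 0 without control replicate 2 or either p63 library. The list of 13 mitochondrially encoded genes had 0 members in the table and was not tested.

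Between p63 and control, edgeR called 1692 genes higher and 1290 lower of 16462 tested, 1339 and 699 of them by at least 2-fold. Scaled by library totals only, the counts were 2220 and 808, the share of higher calls went from 56.7% to 73.3%, and the median of all genes from -0.012 to 0.156. The calls numbered 1098 higher without control replicate 1, 761 higher and 682 lower without control replicate 2, 436 and 177 without p63 replicate 1, and 396 and 186 without p63 replicate 2. With the p63 libraries summed to 1 sample there were 460 and 192 calls. Of the 24 lists camera called 9, and 0 with an estimated correlation, where the lowest adjusted p was 0.137; fry called 8.

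The next comparison set p63 with KLF4 against control. KRT6A, a keratin of activated and appendage epithelium, rose 23800-fold from 0.166 ± 0.0965 to 4240 ± 1250 CPM (log2 14.54, SE 0.63, adjusted p = 2.27e-05). KRT14 rose 10200-fold to 2490 ± 1150 CPM (log2 13.31, SE 0.88, adjusted p = 5.29e-05). PPL, which encodes the cornified envelope protein periplakin, rose 198-fold to 248 ± 56.6 CPM (SE 0.44, adjusted p = 3.44e-05). Of the 28 basal keratinocyte genes 22 rose and 1 fell, and 23 and 1 adjusted over the list alone, with a median of 4.07 (camera adjusted p = 3.89e-16, and adjusted p = 0.00898 with an estimated correlation). The member that fell was not called without any 1 library of control, p63, p63 with KLF4 or the SAM mutant. Of the 28 differentiation and cornification genes 25 rose and 0 fell, and 28 and 0 adjusted over the list alone, with a median of 7.94, or 6.22 with the 12 members at 0 counts in a group at their bound (camera adjusted p = 1.74e-21, and adjusted p = 0.002 with an estimated correlation). Of the 42 junction and polarity genes 32 rose and 1 fell, and 33 and 2 adjusted over the list alone, with a median of 3.46 (camera adjusted p = 7.73e-17, and adjusted p = 0.002 with an estimated correlation). The junction gene that fell was not called without control replicate 1 or either library of p63 with KLF4, and 2 fell without control replicate 2 or SAM mutant replicate 1.

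Several epidermal transcription factors and some signalling genes rose as well. OVOL1, a zinc finger factor of epidermal differentiation, rose 338-fold to 89.6 ± 14.7 CPM (log2 8.40, SE 0.58, adjusted p = 6.33e-05). DLX3, a homeobox factor of suprabasal epidermis, rose 161-fold to 83.9 ± 8.07 CPM (adjusted p = 5.1e-05). Of the 31 epithelial and epidermal transcription regulators 20 rose and 2 fell, and 21 and 2 adjusted over the list alone, with a median of 2.96 (camera adjusted p = 6.29e-08, and adjusted p = 0.121 with an estimated correlation). The number that rose was 12 without control replicate 2, 13 without replicate 1 of p63 with KLF4 and 12 without its replicate 2, and 0 or 1 fell without any 1 library. JAG2, a Notch ligand, rose 23.6-fold to 166 ± 29.8 CPM (log2 4.56, SE 0.26, adjusted p = 3.35e-05). Of 18 Notch pathway genes 6 rose and 3 fell, and 7 and 3 adjusted over the list alone, with a median of 0.52 (camera adjusted p = 0.0691). Those that fell numbered 1 without either library of control or p63 or without replicate 1 of p63 with KLF4, and 0 without its replicate 2. The Wnt ligand WNT7B rose 23.4-fold (SE 0.50, adjusted p = 0.00064). Of 25 Wnt pathway genes 7 rose and 5 fell, and 10 and 6 adjusted over the list alone, with a median of 1.21 (camera adjusted p = 0.089). Those that fell numbered 0 without control replicate 1 or either library of p63 with KLF4, and 3 without either p63 library.

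Some fibroblast genes fell with p63 and KLF4. PRRX1, a homeobox factor of mesenchyme, fell 3.16-fold from 159 ± 11.2 to 50.2 ± 3.06 CPM (log2 -1.66, SE 0.15, adjusted p = 0.000204). Of 53 matrix and identity genes 9 fell and 3 rose, and 10 and 3 adjusted over the list alone, with a median of -0.57 (camera adjusted p = 0.00593, and adjusted p = 0.476 with an estimated correlation). The list call ended without control replicate 2 (adjusted p = 0.148, median -0.18), and the median was also over 1.5 times smaller without replicate 1 of p63 with KLF4. The number that fell was 4 without replicate 1 of p63 with KLF4, and 1 rose without control replicate 1. Of 41 interferon response genes 6 fell and 1 rose, and 2 and 1 adjusted over the list alone, with a median of -0.71 (camera adjusted p = 0.0286, and adjusted p = 0.677 with an estimated correlation). The interferon call ended without control replicate 1 (adjusted p = 0.668, median 0.21) and replicate 2 of p63 with KLF4 (adjusted p = 0.179). The interferon genes that fell numbered 2 and 15 without control replicates 1 and 2 (median -1.16 for the latter), 2 without either p63 library, 1 without either library of p63 with KLF4, and 3 without either SAM mutant library. Of 37 inflammatory genes 4 rose and 3 fell, and 5 and 4 adjusted over the list alone, with a median of -0.05, a mean of 0.36 and a camera direction that was down (adjusted p = 0.784). Of these, 2 rose without control replicate 2 or replicate 1 of p63 with KLF4, 5 fell without control replicate 2 or either DBD mutant library, and 1 fell without replicate 1 of p63 with KLF4.

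Of 24 cholesterol synthesis genes 4 rose and 0 fell, and 7 and 0 adjusted over the list alone, with a median of 0.41 (camera adjusted p = 0.0147, and adjusted p = 0.476 with an estimated correlation). This call ended without replicate 2 of p63 with KLF4 (adjusted p = 0.104), where 1 rose, and 2 rose without control replicate 2, either p63 library or replicate 1 of p63 with KLF4. In the marker lists of other cell types, 3 of 10 endothelial markers rose and 0 fell, 5 and 0 adjusted over the list alone, with a median of 1.36 (camera adjusted p = 0.0286, and adjusted p = 0.317 with an estimated correlation). The endothelial call ended without replicate 1 of p63 with KLF4 (adjusted p = 0.0898), 5 members rose without SAM mutant replicate 1, and the median was 2.39 without control replicate 1. Of the others, 6 of 11 leukocyte markers rose and 0 fell, 6 and 1 adjusted over the list alone, with a median of 1.07 (camera adjusted p = 0.0691). The leukocyte markers that rose numbered 2 without control replicate 1 or replicate 1 of p63 with KLF4, and 3 without control replicate 2 or either p63 library. Also, 4 of 11 muscle markers rose and 0 fell, 5 and 2 adjusted over the list alone, with a median of 0.27 (camera adjusted p = 0.108). In addition, 3 of 11 melanocyte markers fell and 1 rose, also 3 and 1 adjusted over the list alone, with a median of 0.24, a mean of 0.71 and a camera direction that was down (adjusted p = 0.607). The melanocyte markers that fell numbered 1 without either library of control or p63 with KLF4. Of 18 heat shock genes 1 rose and 2 fell, 3 and 4 adjusted over the list alone, with a median of -0.13 (camera adjusted p = 0.504). The heat shock genes that fell numbered 1 without control replicate 1, either p63 library or either library of p63 with KLF4, and 4 without either SAM mutant library, and 2 rose without any 1 library of the mutants.

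Between p63 with KLF4 and control, edgeR called 1936 genes higher and 990 lower, 1663 and 493 of them by at least 2-fold. The number called higher was 1102 without replicate 1 of p63 with KLF4. The number called lower was 613 and 659 without control replicates 1 and 2, 524 and 523 without p63 replicates 1 and 2, and 217 and 448 without replicates 1 and 2 of p63 with KLF4. Camera called 11 of the 24 lists, and 3 with an estimated correlation, which were the basal, differentiation and junction lists; fry called 12.

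**Figure D3:**
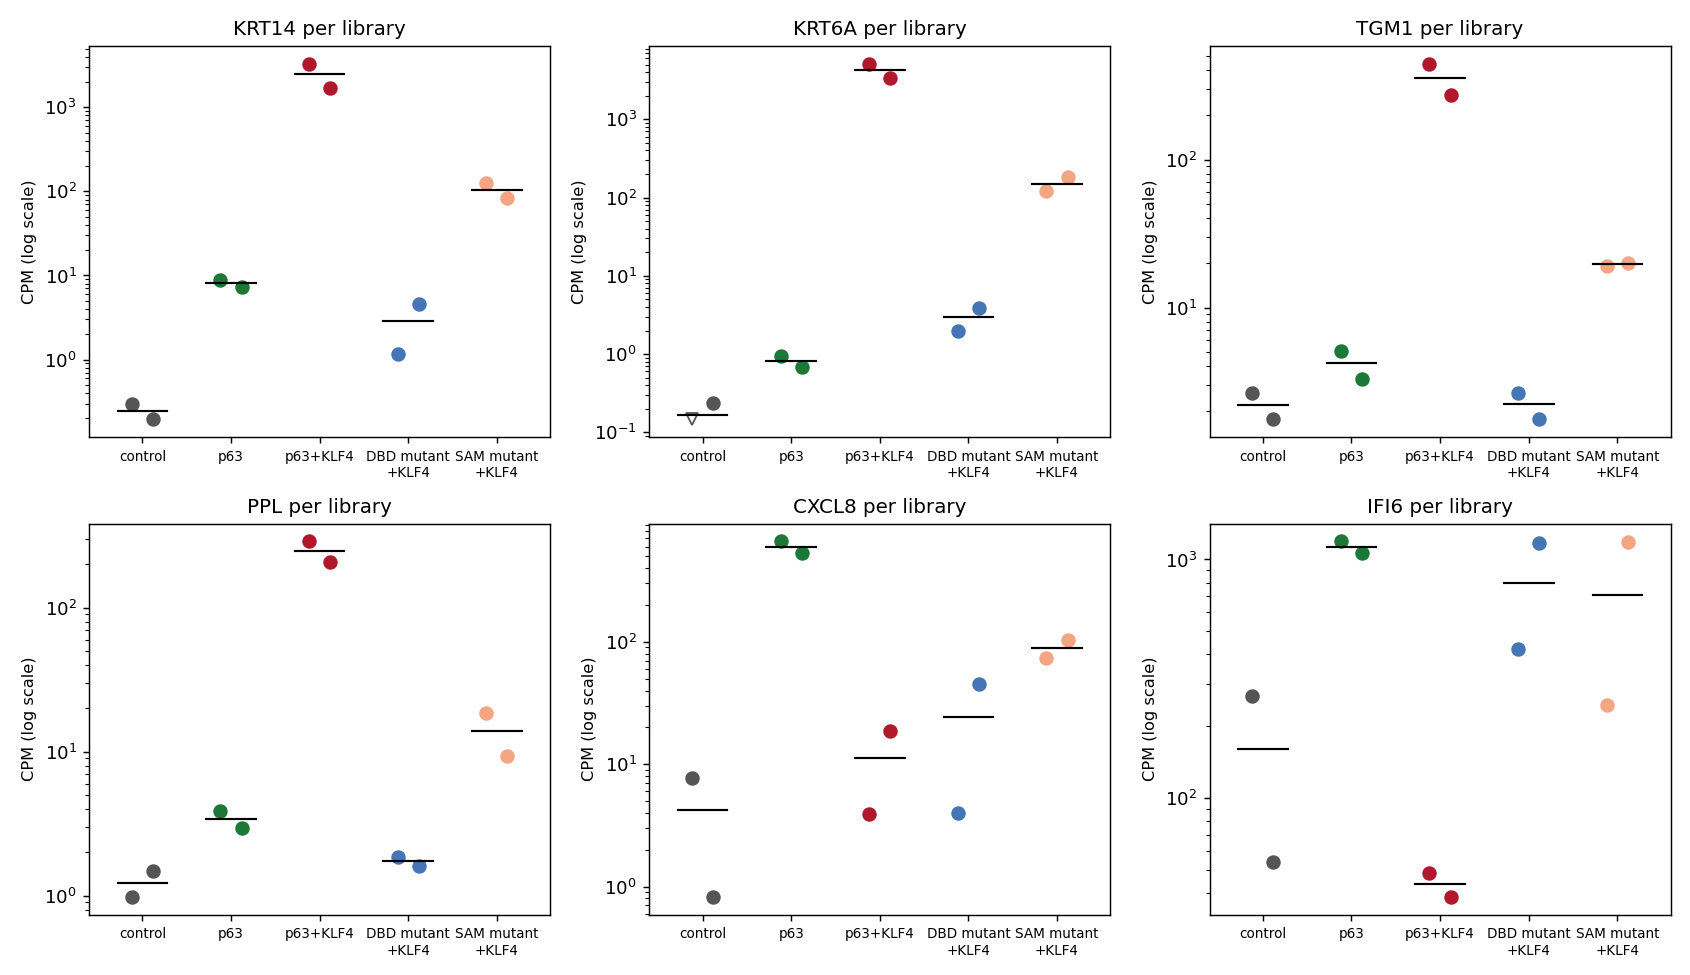
KRT14, KRT6A, TGM1, PPL, CXCL8 and IFI6 in each of the 10 libraries, in CPM on log axes, with points for libraries, black lines for group means, and open triangles at the level of 3 counts for libraries below it. KRT14 stood at 3300 and 1680 CPM in p63 with KLF4, at 126 and 82.7 CPM with the SAM mutant, and at 1.16 and 4.58 CPM with the DBD mutant, while CXCL8 was highest in the p63 pair at 661 and 528 CPM.

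In p63 with KLF4 against p63, added KLF4 and any separate origin of the p63 cells coincide. KRT6A was 5300-fold higher (log2 12.37, SE 0.57, adjusted p = 3.35e-05) and KRT14 312-fold higher (SE 0.69, adjusted p = 0.000195). CDH1, which encodes E-cadherin, rose 11-fold from 1.39 ± 0.119 to 15.3 ± 3.28 CPM (log2 3.46, SE 0.49, adjusted p = 0.00199). Of the 28 differentiation and cornification genes 22 were higher and 1 lower, and 26 and 1 adjusted over the list alone, with a median of 5.95, or 5.25 with the 8 members at 0 counts in a group at their bound (camera adjusted p = 5.15e-14, and adjusted p = 0.00784 with an estimated correlation). The member that was lower was not called without either p63 library or replicate 1 of p63 with KLF4. Of the 42 junction and polarity genes 29 were higher and 3 lower, and 30 and 3 adjusted over the list alone, with a median of 2.51 (camera adjusted p = 1.73e-09, and adjusted p = 0.00784 with an estimated correlation), and 18 and 16 were higher without p63 replicates 1 and 2. Of the 28 basal keratinocyte genes 14 were higher and 0 lower, and 14 and 2 adjusted over the list alone, with a median of 1.21 (camera adjusted p = 2.76e-05, and adjusted p = 0.122 with an estimated correlation). Of the 31 transcription regulators 13 were higher and 1 lower, also 13 and 1 adjusted over the list alone, with a median of 1.08 (camera adjusted p = 0.000894, and adjusted p = 0.389 with an estimated correlation). Those higher numbered 7 and 6 without p63 replicates 1 and 2 and 8 without replicate 1 of p63 with KLF4.

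Many inflammatory genes were lower with p63 and KLF4 than with p63. CXCL2, a neutrophil chemokine, was at 0.124 CPM against 16.7 ± 0.77 CPM with p63, 131-fold lower (log2 -7.04, SE 0.74, adjusted p = 0.000579). CSF3 fell to 3 counts, a ratio of count rates of 181 (95% interval 61.4 to 884). Of 37 inflammatory cytokine and NF-kB genes 24 were lower and 2 higher, and 26 and 3 adjusted over the list alone, with a median of -2.37 (camera adjusted p = 7.84e-09, and adjusted p = 0.389 with an estimated correlation). Those lower numbered 15 without either p63 library. Those higher numbered 0 without either p63 library and 1 without either library of p63 with KLF4. Of 41 interferon response genes 28 were lower and 0 higher, and 31 and 0 adjusted over the list alone, with a median of -1.95 (camera adjusted p = 3.93e-10, and adjusted p = 0.421 with an estimated correlation). That number was 4 and 12 without p63 replicates 1 and 2, and 11 and 3 without replicates 1 and 2 of p63 with KLF4. HOXD10 was higher at a ratio of count rates of 191 (95% interval 65.2 to 929) and HOXD11 was 85.1-fold higher (SE 0.36, adjusted p = 3.86e-05). The p63 pair had the same small spread here.

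Some markers of other cell types differed too. Of 11 muscle markers 6 were higher and 2 lower, also 6 and 2 adjusted over the list alone, with a median of 3.75 (camera adjusted p = 0.0477, and adjusted p = 0.421 with an estimated correlation). The muscle call ended without either library of control (adjusted p = 0.0541 and 0.0534) or of the SAM mutant (0.0565 and 0.056) or p63 replicate 2 (0.0557), the median was 2.38 and 2.43 without replicates 1 and 2 of p63 with KLF4 and 2.45 without p63 replicate 2, 3 were higher and 1 lower without either p63 library, and 1 was lower without replicate 2 of p63 with KLF4. Of 11 melanocyte markers 5 were lower and 1 higher, and 6 and 1 adjusted over the list alone, with a median of -2.15 (camera adjusted p = 0.0153, and adjusted p = 0.421 with an estimated correlation). The melanocyte call ended without either control library (adjusted p = 0.0541 and 0.0534), p63 replicate 2 (0.067) and replicate 2 of p63 with KLF4 (0.073), the median was -1.24 to -1.23 without any 1 library of the groups other than p63 with KLF4, and 1 was lower and 0 higher without any 1 library of p63 or p63 with KLF4. Of 10 endothelial markers 5 were higher and 2 lower, and 6 and 2 adjusted over the list alone, with a median of 1.91 (camera adjusted p = 0.086). Those higher numbered 1 without either p63 library or replicate 1 of p63 with KLF4 and 2 without its replicate 2, and 0 or 1 were lower without any 1 library other than those of the SAM mutant.

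Between p63 with KLF4 and p63, edgeR called 2216 genes higher and 1766 lower, 1590 and 1177 of them by at least 2-fold. These counts were 751 and 465 without p63 replicate 1, 702 and 410 without p63 replicate 2, 1265 and 625 without replicate 1 of p63 with KLF4, and 1361 and 665 without its replicate 2. With the p63 libraries summed to 1 sample they were 767 and 477. Scaled by library totals only they were 1934 and 2051, so that the share of higher calls went from 55.7% to 48.5%. Camera called 11 of the 24 lists, and 2 with an estimated correlation; fry called 15.

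The DBD mutant with KLF4 was set first against control. TP63 (log2 11.76, SE 0.61, adjusted p = 0.000177) and KLF4 (log2 5.22, SE 0.26, adjusted p = 0.000177) were the 2 genes that edgeR called, both higher, and 0 were called lower. At an unadjusted p under 0.05 there were 700 genes. DESeq2 called 18 higher and 2 lower and limma-voom 2 and 0, and edgeR called 3 higher and 1 lower without control replicate 1 and 3 higher without DBD mutant replicate 1. KRT14 stood at 1.16 and 4.58 CPM with the DBD mutant against 0.294 and 0.195 CPM in control, and was not called. In none of the 24 lists was a member called over all genes, and adjusted over the list alone 3 basal keratinocyte genes, 1 differentiation gene and 1 contractile gene were called, the last lower. Camera called 7 lists, 0 of them with an estimated correlation (lowest adjusted p = 0.141), and fry called 0. The basal keratinocyte list had a median of 0.35 (camera adjusted p = 0.000661, and adjusted p = 0.23 with an estimated correlation), the only list of the 7 whose camera call held whichever library was left out, though its median was 0.12 without DBD mutant replicate 2. The differentiation list had a median of 1.79, or 0 with the 12 members at 0 counts in a group at their bound (camera adjusted p = 5.31e-05, and adjusted p = 0.141 with an estimated correlation). The medians were 0.35 for junction genes, 0.42 for transcription regulators, 0.78 for inflammatory genes, or 0.50 with members at 0 counts at their bound, 0.77 for interferon genes and -0.60 for cell cycle genes. Their camera adjusted p were 0.0229, 0.0314, 0.000194, 2.34e-13 and 9.96e-07, and with an estimated correlation the adjusted p was 0.23 for junction genes and 0.484 for each of the other 4. Without control replicate 2 all 6 calls other than basal ended (adjusted p = 0.0561 for differentiation, 0.114, 0.423, 0.776, 0.119 and 0.249 for the others in this order). That of junction genes also ended without control replicate 1 (0.0703) and DBD mutant replicate 1 (0.358), that of regulators without replicates 1 (0.0592) and 2 (0.0597) of p63 with KLF4 and DBD mutant replicate 2 (0.418), and that of inflammatory genes without DBD mutant replicate 2 (0.418). The medians moved too. Without DBD mutant replicate 2 they were 0 for differentiation genes, 0.002 for regulators and 0.05 for inflammatory genes. For inflammatory, interferon and cell cycle genes they were 1.29, 1.91 and -1.14 without control replicate 1 and 0.45, 0.33 and -0.06 without control replicate 2, and for interferon genes 0.46 without DBD mutant replicate 1.

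Against p63 with KLF4, the DBD mutant with KLF4 had lower levels of many epithelial genes. KRT6A was at 2.96 ± 1.35 CPM, 1420-fold lower (log2 -10.47, SE 0.52, adjusted p = 4.3e-05), and KRT14 at 2.87 ± 2.42 CPM, 855-fold lower (SE 0.73, adjusted p = 0.000122). PPL was 142-fold lower at 1.74 CPM (SE 0.43, adjusted p = 5.55e-05). JAG2 was 21.4-fold lower at 7.76 ± 1.88 CPM (SE 0.26, adjusted p = 5.33e-05). Of 28 basal keratinocyte genes 19 were lower and 0 higher, and 23 and 0 adjusted over the list alone, with a median of -3.22 (camera adjusted p = 2.75e-15, and adjusted p = 0.0102 with an estimated correlation). Of 28 differentiation and cornification genes 21 were lower and 0 higher, and 26 and 0 adjusted over the list alone, with a median of -5.93, or -5.61 with members at 0 counts at their bound (camera adjusted p = 4.35e-20, and adjusted p = 0.00236 with an estimated correlation). Of 42 junction and polarity genes 30 were lower and 0 higher, and 31 and 0 adjusted over the list alone, with a median of -3.16 (camera adjusted p = 9.49e-16, and adjusted p = 0.00236 with an estimated correlation). Of 31 transcription regulators 15 were lower and 0 higher, and 19 and 1 adjusted over the list alone, with a median of -2.19 (camera adjusted p = 2.65e-07, and adjusted p = 0.146 with an estimated correlation).

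Some mesenchymal and interferon genes were higher with the DBD mutant than with p63 and KLF4. PRRX1 was 3.06-fold higher (log2 1.61, SE 0.15, adjusted p = 0.00028). Of 53 matrix and identity genes 9 were higher and 2 lower, and 10 and 2 adjusted over the list alone, with a median of 0.45 (camera adjusted p = 0.0193, and adjusted p = 0.538 with an estimated correlation), a call that ended without DBD mutant replicate 1 (adjusted p = 0.219, median 0.14). The median was also over 1.5 times smaller without replicate 1 of p63 with KLF4. The matrix genes that were higher numbered 5 without either p63 library and 4 without replicate 1 of p63 with KLF4 or of the DBD mutant. Those lower numbered 0 and 1 without replicates 1 and 2 of p63 with KLF4, 1 without DBD mutant replicate 2, and 4 without either SAM mutant library. Of 41 interferon response genes 16 were higher and 0 lower, and 23 and 1 adjusted over the list alone, with a median of 1.49 (camera adjusted p = 2.1e-08, and adjusted p = 0.44 with an estimated correlation). That number was 5 and 1 without replicates 1 and 2 of p63 with KLF4 and 7 without DBD mutant replicate 1. The interferon-induced gene IFI6 was 18.3-fold higher (SE 0.95, adjusted p = 0.019), and its call ended without replicates 1 (adjusted p = 0.123) and 2 (0.114) of p63 with KLF4 and DBD mutant replicate 2 (0.0613). The DBD mutant libraries held 422 and 1170 CPM of IFI6, the higher level in the replicate that stood apart on component 3.

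Some markers of other cell types were lower as well. Of 11 leukocyte markers 5 were lower and 0 higher, and 7 and 1 adjusted over the list alone (median -1.75, camera adjusted p = 0.0113, and adjusted p = 0.307 with an estimated correlation), with 3 lower without replicate 1 of p63 with KLF4 or either DBD mutant library. Of 11 muscle markers 5 were lower and 0 higher, and 6 and 1 adjusted over the list alone (median -0.80, camera adjusted p = 0.0201, and adjusted p = 0.307 with an estimated correlation). The muscle call ended without DBD mutant replicate 2 (adjusted p = 0.0796), and 2 were lower without it or replicate 1 of p63 with KLF4, and 1 higher without replicate 2 of p63 with KLF4. Of 10 endothelial markers 2 were lower and 0 higher, and 5 and 1 adjusted over the list alone (median -1.27, camera adjusted p = 0.0265, and adjusted p = 0.304 with an estimated correlation), a call that ended without replicate 1 of p63 with KLF4 (adjusted p = 0.0697), and 4 were lower without control replicate 1 or SAM mutant replicate 1, and the median was -1.97 without DBD mutant replicate 2.

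Between the DBD mutant with KLF4 and p63 with KLF4, edgeR called 909 genes higher and 1731 lower, 499 and 1469 of them by at least 2-fold. The number called higher was 501 and 500 without p63 replicates 1 and 2, 174 and 457 without replicates 1 and 2 of p63 with KLF4, and 433 without DBD mutant replicate 1, and the number called lower was 956 without replicate 1 of p63 with KLF4 and 973 without DBD mutant replicate 1. Camera called 16 of the 24 lists, and 3 with an estimated correlation; fry called 12.

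The SAM mutant with KLF4 was set against control and against both other groups with KLF4. Of 28 differentiation and cornification genes 18 were higher than in control and 0 lower, and 23 and 0 adjusted over the list alone, with a median of 6.10, or 3.29 with the 12 members at 0 counts in a group at their bound (camera adjusted p = 1e-21, and adjusted p = 0.0039 with an estimated correlation), and 7 were higher without control replicate 2. Of 42 junction and polarity genes 16 were higher and 0 lower, and 23 and 2 adjusted over the list alone, with a median of 2.15, or 1.96 with the member at 0 counts at its bound (camera adjusted p = 6.44e-09, and adjusted p = 0.00914 with an estimated correlation). Those higher numbered 10 without control replicate 2 and 9 without SAM mutant replicate 1. Of 28 basal keratinocyte genes 10 were higher and 1 lower, and 15 and 1 adjusted over the list alone, with a median of 1.2 (camera adjusted p = 1.79e-09, and adjusted p = 0.0299 with an estimated correlation), and the 1 lower was not called without any 1 library of control, p63, p63 with KLF4 or the SAM mutant. EdgeR called 838 genes higher than in control and 141 lower, 764 and 74 of them by at least 2-fold. Those called higher numbered 308 without control replicate 2, 555 and 553 without p63 replicates 1 and 2, and 514 without SAM mutant replicate 1. Those called lower numbered 16 without control replicate 2, 41 and 40 without p63 replicates 1 and 2, 75 without either library of p63 with KLF4, and 25 and 45 without SAM mutant replicates 1 and 2. Camera called 11 of the 24 lists, and 3 with an estimated correlation; fry called 9.

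Against p63 with KLF4, some epithelial genes were lower with the SAM mutant, where TP63 itself stood at a log2 fold change of -1.03 (adjusted p = 0.184). KRT6A was 28.1-fold lower at 151 ± 43 CPM (log2 -4.81, SE 0.40, adjusted p = 0.00137) and S100A2 24.1-fold lower at 7.68 ± 2.18 CPM (SE 0.37, adjusted p = 0.00117). TGM1, the transglutaminase that crosslinks the cornified envelope, was 18.3-fold lower at 19.5 ± 0.61 CPM (SE 0.34, adjusted p = 0.00117). Of 28 basal keratinocyte genes 12 were lower and 0 higher, and 19 and 0 adjusted over the list alone, with a median of -1.77 (camera adjusted p = 2.25e-15, and adjusted p = 0.0124 with an estimated correlation), and 4 were lower without SAM mutant replicate 2. Of 28 differentiation and cornification genes 7 were lower and 0 higher, and 15 and 0 adjusted over the list alone, with a median of -1.59 (camera adjusted p = 7.69e-09, and adjusted p = 0.0124 with an estimated correlation). Those lower numbered 4 and 3 without replicates 1 and 2 of p63 with KLF4 (median -0.93 without replicate 1) and 2 without SAM mutant replicate 2. Of 42 junction and polarity genes 15 were lower and 0 higher, and 23 and 0 adjusted over the list alone, with a median of -1.44 (camera adjusted p = 3.59e-14, and adjusted p = 0.00562 with an estimated correlation). That number was 6 and 9 without replicates 1 and 2 of p63 with KLF4 and 5 without SAM mutant replicate 2.

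Some inflammatory genes were higher with the SAM mutant than with p63 and KLF4. Of 37 inflammatory cytokine and NF-kB genes 3 were higher and 0 lower, and 11 and 1 adjusted over the list alone, with a median of 1.10 (camera adjusted p = 3.85e-06, and adjusted p = 0.529 with an estimated correlation). Those 3 were not called without any 1 library of p63, p63 with KLF4 or the SAM mutant, and 5 were called without either control library. Of 41 interferon response genes edgeR called 0, and 0 adjusted over the list alone, with a median of 0.90 (camera adjusted p = 5.6e-08, and adjusted p = 0.529 with an estimated correlation). IFI6 stood at 245 and 1180 CPM in SAM mutant replicates 1 and 2, the higher level again in the replicate that stood apart on component 3, and was not called (log2 4.03, SE 0.94, adjusted p = 0.0698). EdgeR called 73 genes higher and 333 lower than in p63 with KLF4, 47 and 305 of them by at least 2-fold. Those called higher numbered 123 and 125 without control replicates 1 and 2, 13 without either p63 library, 2 and 4 without replicates 1 and 2 of p63 with KLF4, and 21 and 12 without SAM mutant replicates 1 and 2. Those called lower numbered 157 and 154 without p63 replicates 1 and 2, 89 and 129 without replicates 1 and 2 of p63 with KLF4, and 129 and 59 without SAM mutant replicates 1 and 2. Camera called 11 of the 24 lists, and 3 with an estimated correlation; fry called 5.

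The mutants were also set against each other. Of 28 differentiation and cornification genes 14 were higher with the SAM mutant and 0 lower, and 21 and 0 adjusted over the list alone, with a median of 3.64, or 3.41 with members at 0 counts at their bound (camera adjusted p = 3.99e-23, and adjusted p = 0.00335 with an estimated correlation). Those higher numbered 7 and 8 without DBD mutant replicates 1 and 2 and 9 without SAM mutant replicate 1. Of 28 basal keratinocyte genes 9 were higher and 0 lower, and 13 and 0 adjusted over the list alone, with a median of 0.71 (camera adjusted p = 5.74e-09, and adjusted p = 0.0339 with an estimated correlation), or 1.23 and 1.11 without replicate 2 of the DBD and of the SAM mutant. Of 42 junction and polarity genes 12 were higher and 0 lower, and 17 and 0 adjusted over the list alone, with a median of 1.23 (camera adjusted p = 5.74e-09, and adjusted p = 0.00901 with an estimated correlation), and 5 and 6 were higher without DBD mutant replicates 1 and 2 and 5 without SAM mutant replicate 1. Of 10 endothelial markers 3 were higher with the SAM mutant than with the DBD mutant (median 1.32, camera adjusted p = 0.000892, and adjusted p = 0.163 with an estimated correlation) and 3 higher than in control (median 1.63, camera adjusted p = 0.00222, and adjusted p = 0.178 with an estimated correlation), with 0 lower, or 4 and 5 higher adjusted over the list alone. The first 3 were 1 without DBD mutant replicate 1 or SAM mutant replicate 2, and the others 1 without control replicate 1 (median 2.90). Camera also called leukocyte and muscle markers higher in the SAM than in the DBD mutant (adjusted p = 0.0471 and 0.0415, each with adjusted p = 0.438 with an estimated correlation) and leukocyte markers lower than in p63 with KLF4 (adjusted p = 0.0355, and adjusted p = 0.529 with an estimated correlation). Each of these 3 calls ended without either control library, either DBD mutant library or p63 replicate 2 (adjusted p = 0.0575 to 0.18). The first 2 also ended without SAM mutant replicate 2 (0.402 and 0.288), that of muscle without p63 replicate 1 (0.0582), and the last without replicate 1 of p63 with KLF4 (0.214) or of the SAM mutant (0.299). EdgeR called 506 genes higher and 29 lower, 477 and 11 of them by at least 2-fold. Those higher numbered 314 and 313 without p63 replicates 1 and 2, 178 and 322 without DBD mutant replicates 1 and 2, and 283 without SAM mutant replicate 1. Those lower numbered 4 without either p63 library, 11 without either library of p63 with KLF4, 1 without DBD mutant replicate 1, and 2 and 19 without SAM mutant replicates 1 and 2. Camera called 13 of the 24 lists, and 3 with an estimated correlation; fry called 6.

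**Figure D4:**
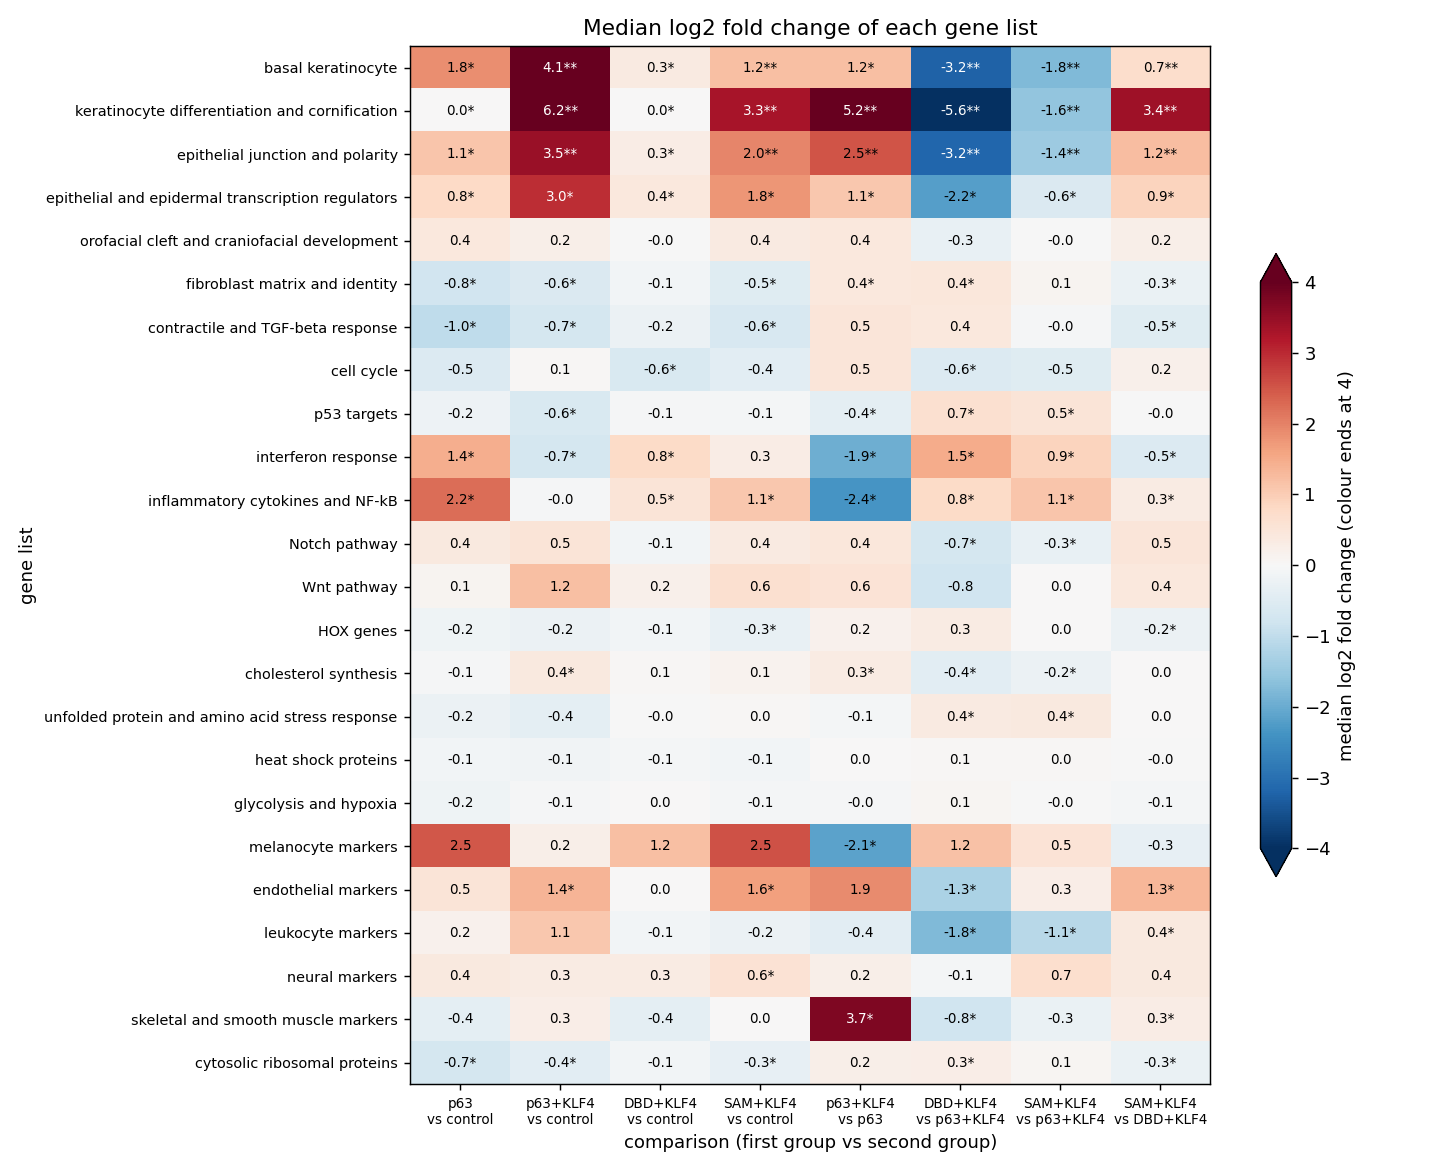
Median log2 fold change of 24 gene lists (vertical axis) in 8 comparisons (horizontal axis), with members at 0 counts at their bound and a colour scale that ends at 4 in both directions. One star marks a camera adjusted p under 0.05 and a pair of stars one that also holds with an estimated correlation; the differentiation list had a median of 6.22 in p63 with KLF4, 3.29 with the SAM mutant and 0 with the DBD mutant, each against control.

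A contrast of contrasts asked whether p63 with KLF4 minus p63 differed from the DBD mutant with KLF4 minus control. The DBD mutant with KLF4 stood in for a group with KLF4 alone, which the labels do not name, so this was not a test of KLF4 alone. LY6G6C, a Ly6-family gene, had a mean of 128 CPM in p63 with KLF4 against 1 count over both p63 libraries, a ratio of count rates of 5310 (95% interval 954 to 210000), and stood at 0.176 CPM in control and 0.292 CPM with the DBD mutant. Its fitted difference of differences, which rests on that count, was 11.55 (SE 2.16, adjusted p = 0.0177). Without control replicate 2 it was 6.26 and the call ended (adjusted p = 1), as it did without p63 replicates 1 (10.98, adjusted p = 0.063) and 2 (14.09, adjusted p = 0.0673). EdgeR called 1394 genes, 770 with a positive and 624 with a negative difference. The number was 764 without control replicate 2, 199 and 171 without p63 replicates 1 and 2, 487 and 555 without replicates 1 and 2 of p63 with KLF4, and 632 without DBD mutant replicate 2. With the p63 libraries summed to 1 sample it was 208. With library totals as the only scaling the share of positive differences went from 55.2% to 45.6% and the median of all genes from 0.023 to -0.096.

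Genes up at least 2-fold with p63 alone were followed in the groups with KLF4. These comparisons share no library with p63 against control, but all tests share a spread estimate, which independent lists ignore. Of these 1339 genes, 418 were lower with the DBD mutant than with p63 and KLF4 and 36 higher, against 140.8 and 73.9 for independent lists, with a median log2 fold change of -0.69. With the SAM mutant 117 were lower and 10 higher, against 27.1 and 5.9, with a median of -0.22. Between the mutants 147 were higher with the SAM mutant and 0 lower, against 41.2 and 2.4. The number lower with the DBD mutant was 267 without control replicate 2, 178 and 167 without p63 replicates 1 and 2, and 263 without replicate 1 of p63 with KLF4. With the SAM mutant it was 38 and 33 without p63 replicates 1 and 2, 32 and 45 without replicates 1 and 2 of p63 with KLF4, and 56 and 27 without SAM mutant replicates 1 and 2. Of the 699 genes lower by at least 2-fold with p63, 158 were higher and 47 lower with the DBD mutant than with p63 and KLF4, against 38.6 and 73.5, and 16 were higher and 14 lower with the SAM mutant, against 3.1 and 14.1. Between the mutants 18 were higher with the SAM mutant and 13 lower, against 21.5 and 1.2.

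Across the 16462 genes, which are not independent replicates, log2 fold changes of p63 against control correlated with those of the DBD mutant against p63 with KLF4 at r = -0.282 and rho = -0.212. With the SAM mutant against p63 with KLF4 they were -0.139 and -0.096, and with the SAM against the DBD mutant 0.291 and 0.245. Without DBD mutant replicates 1 and 2 the first r was -0.179 and -0.425, without SAM mutant replicates 1 and 2 the next was -0.052 and -0.291, and the last was 0.069 without SAM mutant replicate 2, 0.148 without DBD mutant replicate 1 and 0.452 without DBD mutant replicate 2. The change from p63 to p63 with KLF4 and that from control to the DBD mutant with KLF4 correlated at r = 0.028 and rho = -0.062, with r between -0.024 without DBD mutant replicate 1 and 0.059 without control replicate 2.

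Calls that share libraries overlapped. Of the genes higher than in control, 619 were shared between p63 and p63 with KLF4, against 199 for independent lists, and of the lower genes 310 against 77.6, while 34 were higher with p63 and lower with p63 and KLF4, and 71 the reverse. The r of the fold changes was 0.50 against 0.504 in simulations of unchanged groups, and the covariance 1.243 against a simulated 0.128. Between p63 with KLF4 and the SAM mutant, 754 higher genes were shared against 98.6, and 121 lower genes against 8.5, with r = 0.87 against a simulated 0.507 and a covariance of 2.095 against 0.13. Against p63 with KLF4, the DBD and SAM mutants shared 330 lower genes against 35 and 55 higher against 4, with r = 0.737 against a simulated 0.47 and a covariance of 0.948 against 0.117. Simulated overlaps averaged 0 to 0.1 over 20 simulations, and part of each excess may come from the shared libraries, which were not split, since that leaves 1 in each part. Of the 1731 genes lower with the DBD mutant than with p63 and KLF4, edgeR called 665 higher with the SAM mutant than in control and 0 lower, against 88.1 and 14.8 for independent lists, with a median of 2.52 for p63 with KLF4 over the DBD mutant and 1.41 for the SAM mutant over control. Of the 909 genes higher with the DBD mutant, 89 were lower with the SAM mutant than in control and 6 higher, against 7.8 and 46.3, with medians of -1.06 and -0.39.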

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

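Chosen after seeing the data were settings that sum or drop the p63 pair, drop both mutants' replicates 2 or give these a batch term. No result was called both ways, but some list medians changed sign. Of 450 results for named genes 412 were called, and 195 of these stayed called in every setting. Of 192 list results 89 were called, and 17 stayed called in every setting. Depth limits the low genes, since 3 counts in a library correspond to 0.0743 to 0.201 CPM. The cause of a change was not tested, except that a stricter threshold calls fewer genes by construction. When a library was left out, the lone library of its group was assumed to vary like the other groups.

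Leaving out each library in turn gave 396 to 1895 genes higher and 177 to 1382 lower in p63 than in control, 1102 to 2136 and 217 to 1050 in p63 with KLF4 than in control, 2 to 3 and 0 to 1 with the DBD mutant than in control, and 308 to 1008 and 16 to 202 with the SAM mutant than in control. It gave 702 to 2411 genes higher and 410 to 1922 lower in p63 with KLF4 than in p63. Against p63 with KLF4 it gave 174 to 1074 higher and 956 to 1919 lower with the DBD mutant and 2 to 125 and 59 to 391 with the SAM mutant, and 178 to 539 and 1 to 36 in the SAM against the DBD mutant. The contrast of contrasts had 171 to 1523 calls, and the p63-induced genes lower than in p63 with KLF4 numbered 167 to 456 with the DBD mutant and 27 to 131 with the SAM mutant. The correlations of p63 against control ran from -0.425 to -0.179 with DBD mutant against p63 with KLF4, from -0.291 to -0.052 with SAM mutant against p63 with KLF4, and from 0.069 to 0.452 with SAM against DBD mutant. That of p63 with KLF4 against p63 with DBD mutant against control ran from -0.024 to 0.059.

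With library totals only, 808 genes were lower in p63 than in control. Without a filter on low counts 8 genes were higher with the DBD mutant than in control, 140 were higher and 567 lower with the SAM mutant than in p63 with KLF4, 48 were lower in the SAM than in the DBD mutant, 193 p63-induced genes were lower with the SAM mutant, and the correlation of p63 against control with SAM against DBD mutant was 0.173. DESeq2 called 18 higher and 2 lower with the DBD mutant than in control, 417 lower with the SAM mutant than in control, 337 higher and 718 lower with the SAM mutant than in p63 with KLF4, 850 higher and 164 lower in the SAM than in the DBD mutant, 2679 in the contrast of contrasts, and 233 p63-induced genes lower with the SAM mutant. In fits of only the groups compared, 513 genes were lower in p63 with KLF4 than in control, 436 higher and 7 lower with the SAM mutant than in control, 3793 higher and 3476 lower in p63 with KLF4 than in p63, 487 higher with the DBD mutant and 45 higher with the SAM mutant than in p63 with KLF4, and 45 higher and 0 lower in the SAM than in the DBD mutant. With TP63 and KLF4 left out 0 genes were higher with the DBD mutant than in control.

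At an adjusted p under 0.01 there were 541 higher and 365 lower in p63 than in control, 1029 and 276 in p63 with KLF4 than in control, 313 and 10 with the SAM mutant than in control, 1041 and 603 in p63 with KLF4 than in p63, 223 and 896 with the DBD mutant and 6 and 104 with the SAM mutant than in p63 with KLF4, 207 and 1 in the SAM than in the DBD mutant, 269 in the contrast of contrasts, and 157 and 30 p63-induced genes lower with the DBD and the SAM mutant. With a minimum change of 2-fold the lower genes numbered 699 in p63, 493 in p63 with KLF4 and 74 with the SAM mutant, each against control, 1177 in p63 with KLF4 against p63, and 11 in the SAM against the DBD mutant, and 499 and 47 were higher with the DBD and the SAM mutant than in p63 with KLF4.

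Under the replicate block 110 genes were higher with the SAM mutant than in p63 with KLF4 and 44 were lower in the SAM than in the DBD mutant. With it 4 named-gene calls and 6 list calls ended, and 1 named-gene call and 3 list calls were added in the direction of the main run. The pairing check correlated deviations of libraries with the same number: r was 0.696 between the mutants, 0.349 and 0.252 between control and the SAM and DBD mutants, -0.225 between control and p63 with KLF4, and -0.037 to 0.036 elsewhere. Control and both mutants thus deviated together by number. With 2 libraries a group, other groups that did not, and no label that ties the numbers to a batch, the numbers were not read as pairing. Under the block no other count of genes called in a comparison moved by over 1.5 times.

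With the p63 libraries summed to 1 there were 460 higher and 192 lower in p63 than in control, 524 lower in p63 with KLF4 than in control, 553 higher and 40 lower with the SAM mutant than in control, 767 higher and 477 lower in p63 with KLF4 than in p63, 501 higher with the DBD mutant and 13 higher and 155 lower with the SAM mutant than in p63 with KLF4, 313 higher and 4 lower in the SAM than in the DBD mutant, 208 in the contrast of contrasts, and 187 and 38 p63-induced genes lower with the DBD and the SAM mutant. With the p63 group left out, 542 were lower in p63 with KLF4 and 42 with the SAM mutant than in control, 515 were higher with the DBD mutant and 13 higher and 157 lower with the SAM mutant than in p63 with KLF4, and 315 were higher and 4 lower in the SAM than in the DBD mutant. With replicate 2 of both mutants left out, 77 were lower with the SAM mutant than in control, 46 higher and 176 lower than in p63 with KLF4, 11 lower in the SAM than in the DBD mutant, and the correlations of p63 against control were -0.427 and -0.295 with the DBD and SAM mutants against p63 with KLF4. The batch term gave 2578 higher and 2199 lower in p63 than in control, 1868 lower in p63 with KLF4 and 4 higher with the DBD mutant than in control, 2742 lower in p63 with KLF4 than in p63, 1644 higher with the DBD mutant and 298 higher and 678 lower with the SAM mutant than in p63 with KLF4, 803 higher and 119 lower in the SAM than in the DBD mutant, and 720 and 292 p63-induced genes lower with the DBD and the SAM mutant. Its correlations were -0.41 and -0.341 with the DBD and SAM mutants against p63 with KLF4, and 0.136 between p63 with KLF4 against p63 and DBD mutant against control.

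Named-gene calls ended numbered 5 with median-of-ratios size factors, 19 with library totals, 5 with no filter, 13 with a minimum mean of 1 CPM, 2 with DESeq2, 43 with limma-voom, 45 in fits of only the groups compared, 181 at an adjusted p under 0.01, 24 with a minimum of 2-fold, 140 with the p63 pair summed, 53 without the p63 group, 42 without replicate 2 of both mutants and 4 with the batch term. List calls ended numbered 72 with an estimated correlation in camera and 42 with fry, 2 with median-of-ratios size factors, 6 with library totals, 9 with no filter, 4 with a minimum mean of 1 CPM, 7 without the p63 group, 17 without replicate 2 of both mutants and 14 with the batch term. Those added in the direction of the main run were 0, 20, 1, 3, 11, 9, 1, 8 and 6 in this order.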

Other observations

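Among the tests of explanations, that on the few calls with the DBD mutant was set before its result was seen. Those on the mutants' second replicates and the HOXD genes were chosen after results were seen.

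Some genes outside the rule for named genes were chosen after their values were seen. H19, an imprinted noncoding RNA, stood at 663 and 637 CPM in p63 with KLF4 and 660 and 168 CPM with the SAM mutant, against 5.4 and 2.37 CPM with the DBD mutant, 0.735 and 2.5 in control, and 0.671 and 0.577 with p63. By edgeR it was higher than in control in p63 with KLF4 (log2 8.61, SE 0.88, adjusted p = 0.000444) and with the SAM mutant (log2 7.96, SE 0.86, adjusted p = 0.00152). Of 10 kallikrein genes tested, 10 were higher in p63 with KLF4 than in control and 9 lower with the DBD mutant than in p63 with KLF4. With the SAM mutant 7 were higher than in control, and 4 without either control library, and 4 were lower than in p63 with KLF4 (median log2 -2.66), but 0 without either library of p63 with KLF4 or SAM mutant replicate 2, and 2 without either p63 library or SAM mutant replicate 1.

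The DBD mutant with KLF4 differed from control in 2 genes by edgeR, TP63 and KLF4, with 700 genes at an unadjusted p under 0.05 and 18 higher and 2 lower by DESeq2. A wide spread from DBD mutant replicate 2 could hide changes. A fit without that library leaves 1 in the group and cannot decide this. Changes not called stay open: simulations recovered 18% and 62% of genes changed by 1 and 2 log2 units here. Their equal group spread may overstate recovery.

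Replicates 2 of the DBD and SAM mutants deviated together from their group means. CCND2, a cyclin, stood at 268 and 126 CPM in them and 1.77 and 1.23 in replicates 1. C3, a complement gene, stood at 135 and 170 against 2.56 and 6.72 CPM, but at 1130 and 1150 in p63. Of 91 genes selected as at least 4-fold higher in both than in replicates 1, 41 (45.1%) exceeded all 8 other libraries. This argues against a mixture with another group for these genes. For the rest, cells or RNA of the p63 group may contribute: over 12 genes specific to p63 the share of the p63 level had a median of 4.61% and 5.79%, and its 90th percentile was 10.3 and 7.83 times its 10th, which leaves this open. A shared culture or library batch (r = 0.696 between the deviations of these libraries) also stays open, since replicate 2 of control correlated with them at 0.30, p63 at -0.036 and p63 with KLF4 at 0.004, and the labels name no batch.

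HOXD9, HOXD10 and HOXD11 were near 0 in both p63 libraries and in no other library, with HOXD10 at 0.0671 and 0.077 CPM against 13.2 and 15 CPM in p63 with KLF4. Lower depth of the p63 libraries is argued against, since 1343 counts were expected at the level of the other libraries and 19 were seen (95% upper limit 29.7). An effect of p63 with or without KLF4 as the whole cause is argued against by the levels in p63 with KLF4, at least 4.88 (log2) above p63 and at log2 -0.24 (SE 0.40), -0.11 (SE 0.23) and 0.12 (SE 0.24) against control, values that were part of the pattern as noticed, the first taken up as the test after the others had been read as leaving it open. A separate starting population of cells for the p63 libraries could also give this: 5 genes, these 3 among them, were under 0.3 CPM in both p63 libraries and over 3 CPM in each of the other 8, against 0 for p63 with KLF4, while 11 and 9 genes were over 3 CPM in both libraries of p63 and of p63 with KLF4 and under 0.3 CPM elsewhere. This cannot be told from an effect of p63 only without KLF4, which was not tested, as population and group coincide in all p63-group comparisons.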
